A study of Homo sapiens with 18 samples.

How the data were processed

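The measurements were the read counts per gene deposited for 18 libraries of polyadenylated RNA. Per the submitters' processing notes, base calls were made with CASAVA 1.8, reads were mapped with HISAT2 2.1.0 to the human genome build hg38, and reads per gene were counted with HTSeq 0.11.3. The deposited count table was used as it stood. The notes give neither the gene annotation nor whether counting used the strand. The table held 58721 gene identifiers, all present in GENCODE 29, of which 45 were copies on the Y chromosome of pseudoautosomal genes; 58207 had a current symbol. Cells were grown in RPMI1640 with 10% serum, per the labels.

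Sample groups, comparisons, gene lists, named gene rule and alternatives were fixed before the data were examined. The 10 comparisons were KO1 and KO2 with ctl, FL, Y47A and dN with KO1, Y47A and dN with FL, dN with Y47A, FL with ctl and KO2 with KO1. The groups labelled WT and NTT in the sample titles were taken as FL and dN from their genotype labels. Rescued cells came from KO1, so their restoration was counted on genes called in KO2. Counts were filtered with filterByExpr (smallest count 10), which left 22794 genes, scaled with TMM (factors 0.928 to 1.05) and fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, all 18 libraries together. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene is called at an adjusted p under 0.05. CPM used TMM-scaled totals, and log2 CPM for scores and components used a prior count of 2.

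Library totals ran from 51860694 to 94959253 counts. Mitochondrial genes held 1.70% to 2.01% of counts in ctl and 1.99% to 2.56% in the other groups. Replicate numbers were tested as possible pairs: same-number libraries of ctl and KO1 correlated at 0.105, 0.332 and 0.184 over 10259 genes after removal of group means, and no other comparison had all 3 above 0.1. The numbers were therefore left out of the fit and tried as a replicate block.

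Named genes were taken by rule: the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap of CPM between the groups, without pseudogenes, antisense or clone names or sex-linked genes. This was done for the knockouts (called alike in both, ranked by the smaller change), FL with KO1, Y47A with FL and dN with FL. Genes of a list were named only if they were among its 4 smallest p-values in that comparison, and called subunits of the TIP60 complex were named wherever that list is described. Values of these genes in other comparisons were given for genes chosen after the values had been seen. Of 37 named genes, 13 overlapped another tested gene and 6 overlapped one within 2 log2 CPM or above, by means over all 18 libraries. KAT5 was not among the 6, since overexpression raised its mean log2 CPM to 7.16, against 4.08 for the overlapping RNASEH2C. In ctl and the knockouts KAT5 stood far lower.

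The 35 gene lists (746 genes, 2 without an identifier) were written from general knowledge: TIP60 complex, other histone acetyltransferases, ribosomal proteins, ribosome biogenesis, tRNA synthetases, MYC targets, mitosis, DNA replication, histones, double-strand break repair, p53 targets, interferon-stimulated genes, NF-kB, integrated stress response, unfolded protein response, heat shock proteins, cholesterol biosynthesis, hypoxia and glycolysis, nuclear and mitochondrially encoded respiration genes, lysosome, matrix, junction, mesenchymal, TGF-beta targets, YAP/TEAD targets, immediate early genes, apoptosis, housekeeping and markers of 6 other cell types. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison; the lung epithelium markers had 4 tested genes and were not tested. Camera with an estimated correlation and the self-contained test fry were alternatives. List medians were also computed with library totals in place of TMM.

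The KO2-response score of a library was the mean log2 CPM of genes raised in KO2 minus that of genes lowered; ctl and KO2 chose the genes and were left out of the tests. Score differences were tested by exact two-sided permutation, whose smallest p for 3 against 3 is 0.1. Overlaps of comparisons with shared controls were set beside 10 simulations of groups without change, drawn from the mean levels, library sizes and dispersions of the data. Alternatives for counts were RLE factors, library totals, a filter at a mean CPM of 1, all genes with a count, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, an adjusted p under 0.01, a 2-fold change and leaving out each library in turn; counts thinned to the smallest library, and for the knockout lists a comparison of each member with the 200 other genes nearest in level midway between ctl and the knockouts, were added after the data had been seen. Scores were repeated with a prior count of 0.5 and other gene sets. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

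The code was tested on negative binomial counts simulated from the mean levels, library sizes and dispersions of the data, with 200 genes changed in KO1 by known factors. It recovered 48%, 50%, 64% and 82% of the 50 genes each that were changed 1.2-fold, 1.5-fold, 2-fold and 3-fold, all in the right direction, and called 7 of 21981 unchanged genes. In a second simulation a list of 40 genes lowered 1.2-fold was called, as was 1 of 33 other lists. The MYC targets among those 33 share NCL and NPM1 with the lowered list, so not all of them were unchanged. The score was checked only on simulated genes with a mean log2 CPM of at least 3, where it came within a preset margin of the simulated difference. It was not checked on genes of lower level, which the score as used includes.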

Results

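Messenger RNA was measured by sequencing in 18 libraries of H1299, an established human lung carcinoma cell line that lacks p53. The libraries fell into 6 groups of 3. The control group (ctl) carried a guide RNA against GFP, a gene that human cells do not have, and the groups KO1 and KO2 were lines with TIP60 knocked out. TIP60, encoded by KAT5, is the lysine acetyltransferase of a chromatin complex that also remodels nucleosomes. The remaining groups were KO1 cells made to overexpress TIP60 in its full-length form (FL), with the substitution Y47A, or in a form labelled dN. The title of the series names the Tudor-knot domain of TIP60 as its subject, so the comparisons ask what the knockout changed and how far each form moved the cells back. Library totals ran from 51860694 to 94959253 counts, and the smallest belonged to dN replicates 2 and 3 (51860694 and 53132491). The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as counts scaled by library size (CPM, mean ± SD, n = 3 libraries), changes as log2 fold changes ± SE, and a gene is called at an edgeR adjusted p under 0.05 among 22794 genes tested. The first principal component held 45.3% of the variance and placed ctl and FL on one side and the other groups on the other.

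**Figure D1:**
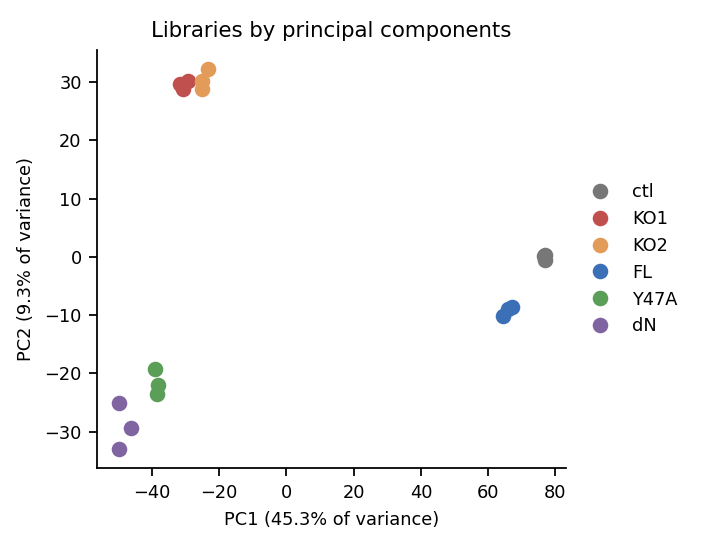
Each point is 1 library, placed by its first and second principal components (45.3% and 9.3% of the variance of log2 CPM) and coloured by group. The ctl and FL libraries lie at high values of the first component, and KO1, KO2, Y47A and dN at low values.

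KAT5 mRNA was lower in both knockouts and far higher in all 3 groups that overexpressed it. KAT5 (ENSG00000172977, chromosome 11, 65711996 to 65719604, plus strand, hg38) stood at 14.0 ± 0.41 CPM in ctl, 10.6 ± 0.94 in KO1 and 10.9 ± 0.50 in KO2. It fell by 0.40 ± 0.05 on the log2 scale in KO1 (adjusted p = 1.54e-09) and by 0.36 ± 0.05 in KO2 (adjusted p = 2.64e-08). FL libraries held 1715 ± 54.1 CPM, Y47A libraries 1860 ± 24.5 and dN libraries 1669 ± 17.1, so that FL exceeded KO1 by 7.34 ± 0.04 (adjusted p = 3.44e-47). The Y47A form was slightly above FL (0.12 ± 0.03, adjusted p = 0.00107), whereas dN and FL were not told apart (-0.04 ± 0.03, adjusted p = 0.277). These levels went with the knockout and overexpression labels, but gene counts cannot tell the 3 forms apart. A frameshift can leave much of the mRNA in place, and protein levels are not among these data. KAT5 also overlaps RNASEH2C on the opposite strand, whose reads cannot be separated if the counting ignored strand.

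**Figure D2:**
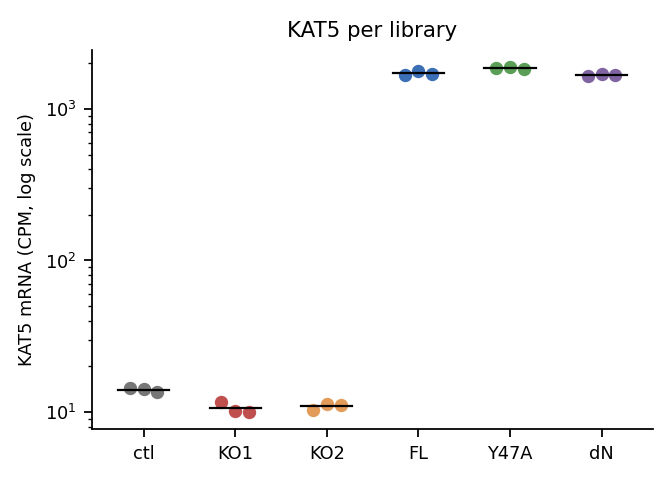
KAT5 mRNA in CPM on a log axis for each library, with points for the 3 libraries of a group and a bar at their mean. The group means are 14.0 (ctl), 10.6 (KO1), 10.9 (KO2), 1715 (FL), 1860 (Y47A) and 1669 (dN).

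Among genes with a mean log2 CPM of at least 3, EDIL3 and CPA4 headed those that rose in both knockouts, and SPP1 and TEAD2 those that fell. EDIL3, a secreted integrin ligand (ENSG00000164176, chromosome 5, 83940554 to 84384793), rose from 1.77 ± 0.41 CPM in ctl to 28.5 ± 3.05 in KO1 and 28.4 ± 1.37 in KO2, a log2 fold change of 4.01 ± 0.11 in KO1 (adjusted p = 4.6e-26; KO2 adjusted p = 9.36e-26). CPA4, a secreted carboxypeptidase, rose by 4.02 ± 0.09 and 3.73 ± 0.09, and the receptors NEO1 (3.08 and 2.93) and EPHB2 (2.57 and 2.33) and the calcium-binding protein gene CALB2 (3.17 and 2.81) followed. TGFBI, a matrix protein induced by TGF-beta, went from 101.2 ± 2.78 CPM to 471 ± 13.2 and 453 ± 10.8. NRCAM, BHLHE40, ADGRB2 and ZCCHC24 completed the 10 largest rises at that level, all of at least 2.04 in both lines. SPP1, which encodes osteopontin (ENSG00000118785, chromosome 4, 87975650 to 87983426), fell from 45.2 ± 0.41 CPM to 13.0 ± 0.97 and 16.0 ± 0.63 (adjusted p = 3.33e-21 and 5.63e-19), which in KO2 was a fall by 1.49 ± 0.07 on the log2 scale. TEAD2, a DNA-binding partner of YAP, fell from 34.7 ± 0.93 CPM to 9.23 ± 0.54 and 12.9 ± 0.83. The ETS factor gene ETV4 (-1.55 and -1.43), the collagen chaperone gene SERPINH1 (-1.36 and -1.12) and ANP32E, a chaperone of a histone variant (-1.32 and -1.15), were among the other largest falls, with MEX3A, TNNT1, GRIN2D, VGF and DDAH2. ETV4 overlaps the expressed gene DHX8 and DDAH2 overlaps CLIC1, so reads of these pairs may be split uncertainly.

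**Figure D3:**
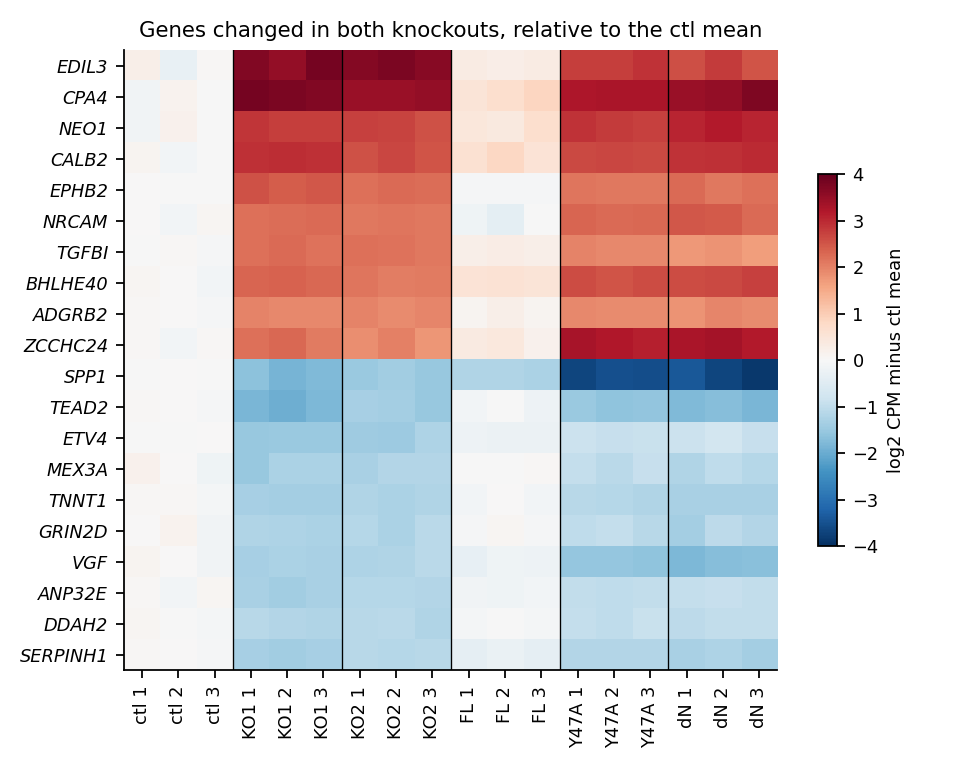
Each cell is the log2 CPM (0.5 added) of a gene in 1 library minus its ctl mean, for the 10 largest rises and 10 largest falls shared by both knockouts among genes with a mean log2 CPM of at least 3. EDIL3 and SPP1 head the rises and falls; FL libraries lie near ctl for most genes, and the Y47A and dN libraries nearer the knockouts, with SPP1 lower still.

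Genes of protein synthesis fell in both knockouts. Of 52 cytosolic ribosomal protein genes, 50 were lower and 2 not called in KO1 (median log2 fold change -0.41, camera adjusted p = 2.75e-30), and 51 were lower and 1 not called in KO2 (-0.34, adjusted p = 1.23e-28). RPL6 fell by 0.56 and 0.52 on the log2 scale. All 40 ribosome biogenesis genes were lower in KO2 and 38 of them in KO1, with medians of -0.43 (camera adjusted p = 3.77e-21) and -0.44 (adjusted p = 2.43e-18). Their examples were the nucleolar methyltransferase gene FBL (-0.71 and -0.70) and NOP56 (-0.61 and -0.64). Among 20 tRNA synthetase genes, 3 were higher and 16 lower in KO1 and 2 higher and 16 lower in KO2 (adjusted p = 1.52e-07 and 1.17e-08), with EPRS1 at -0.71 and -0.63. MYC target genes followed, with 2 of 25 higher and 20 lower in each line (medians -0.45 and -0.41, adjusted p = 1.32e-10 and 2.56e-11), led by the mitochondrial chaperone genes HSPD1 (-0.88 and -0.81) and HSPE1 (-0.96 and -0.90). Adjusted over the list alone, the counts were the same except for 17 lower tRNA synthetase genes in each line and 21 lower MYC targets in KO2. Many ribosomal protein and chaperone genes have processed pseudogenes that can share their reads.

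Cell cycle, DNA repair and energy genes were also lower. DNA replication genes fell, with 4 of 34 higher and 25 lower in KO1 and 3 higher and 23 lower in KO2 (camera adjusted p = 5.76e-06 and 4.02e-06), such as MCM7 (-0.49 in each line) and RRM2 (-0.73 and -0.64), while the cyclin gene CCNE1 rose by 0.92 and 0.86. Of 32 mitosis genes, 28 were lower in KO1 and 27 in KO2 (medians -0.32 and -0.28), including UBE2C (-0.67 and -0.68) and the kinesin gene KIF11 (-0.63 and -0.55). Camera called them (adjusted p = 2.14e-11 and 1.45e-10), but not with an estimated correlation (adjusted p = 0.0732 and 0.0835 with an estimated correlation). Double-strand break repair genes were lower for 22 and 21 of 32 (adjusted p = 7.17e-06 and 4.02e-06; for KO1 adjusted p = 0.056 with an estimated correlation), among them XRCC5 (-0.56 and -0.51) and PRKDC (-0.38 and -0.39), while 2 were higher in each. Genes of other histone acetyltransferases and their partners fell in 15 of 21 cases in each line (adjusted p = 9.14e-05 and 5.5e-05), with MSL1 at -0.78 and -0.69 and JADE2 at -0.66 and -0.63. The called falls of heat shock proteins (9 of 13 in each; HSP90AB1 -0.65 and -0.63), hypoxia and glycolysis genes (15 and 14 of 27; GPI -0.69 and -0.62) and nuclear oxidative phosphorylation genes (22 and 21 of 32; ATP5F1B -0.52 in each) did not hold (adjusted p = 0.067 to 0.309 with an estimated correlation). In the glycolysis list HK1 went the other way, by 1.13 and 1.04, and the list's median in KO2 was -0.14 with TMM and 0.00 with library totals. With p-values adjusted over the list alone, the KO1 counts were unchanged for these 7 lists, and in KO2 24 replication, 22 repair and 16 acetyltransferase genes were lower and 1 mitosis gene higher.

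Extracellular matrix, epithelial junction, lysosome and histone genes rose. Of 26 matrix genes, 19 were higher and 3 lower in KO1 and 20 higher and 2 lower in KO2 (medians 1.14 and 0.92, camera adjusted p = 1.24e-08 and 1.17e-08). The fibronectin gene FN1 rose from 49.1 ± 0.91 CPM to 194 ± 5.66 and 196 ± 9.40 (log2 fold change 1.98 ± 0.05 in KO1), and the collagen VI gene COL6A2 by 1.67 and 1.54. Epithelial junction genes were higher in 14 and 15 of 18 cases and lower in 1 (medians 1.06 and 0.96, adjusted p = 1.24e-05 and 3.42e-05), with the keratin gene KRT8 (1.33 and 1.21) and the plakoglobin gene JUP (1.76 and 1.53). Mesenchymal genes rose as well, with 10 and 11 of 17 higher and 4 lower (adjusted p = 0.00256 and 0.00727; VIM 0.39 and 0.35). TGF-beta targets were higher in 13 of 17 cases in each line and lower in 2 (adjusted p = 1.23e-05 and 4.02e-06), such as PMEPA1 at 1.86 and 1.68. Lysosome and autophagy genes were higher in 20 and 19 of 26 cases and lower in 2 (adjusted p = 9.49e-08 and 1.15e-07), with the autophagy receptor gene SQSTM1 at 0.95 and 0.82. Replication-dependent histone genes were higher in 9 of 16 cases, lower in 1 (KO1) and 2 (KO2) (medians 0.72 and 0.78, adjusted p = 0.000109 and 0.000123), led by H2AC11 (1.81 and 1.76). These histone genes are near-identical copies whose mRNA mostly lacks a poly(A) tail, so their counts are uncertain. Mitochondrially encoded genes were higher in 13 of 13 and 10 of 13 cases (medians 0.25 and 0.22, camera adjusted p = 0.000161 and 0.00162), but not with an estimated correlation (adjusted p = 0.328 and 0.418 with an estimated correlation). Adjusted over the list alone, 20 matrix, 15 junction and 14 TGF-beta genes were higher in KO1, and 20 lysosome genes were higher and 3 matrix genes lower in KO2, with the other counts as given.

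Markers of other cell types moved with these rising lists at low levels. Leukocyte markers were higher in 4 of 8 cases in each knockout, endothelial markers in 6 and 5 of 7 and fibroblast markers in 5 and 4 of 6 (5 in KO2 adjusted over the list alone), although camera called none of these lists (adjusted p = 0.0534 to 0.0838). The integrin gene ITGAM went from 2.61 CPM in ctl to 10.3 and 9.21, COL1A1 from 1.43 to 7.02 and 6.26, and KDR from 0.473 to 3.28 and 2.79. PTPRC rose as well but reached only 0.346 CPM in KO1, and its call in KO2 was lost when certain single libraries were left out. Of 8 neuroendocrine markers 3 and 5 were higher (ENO2 0.41 and 0.40), and markers of HEK293 or HeLa lineage went both ways (4 higher and 4 lower in KO1, 4 higher and 3 lower in KO2; LIN28B -0.70 and -0.67), with no call by camera for either list (adjusted p = 0.0547 to 0.848). Housekeeping genes were lower in 8 of 13 cases in each line and higher in 2, among them GAPDH at -0.28 in each, but their median of -0.08 (KO1) and -0.11 (KO2) with TMM became 0.05 and 0.03 with library totals. Camera called them at adjusted p = 0.011 and 0.0191 (adjusted p = 0.109 and 0.131 with an estimated correlation).

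The TIP60 complex itself changed unevenly. Of its 18 genes, 5 were higher and 9 lower in KO1 and 4 higher and 8 lower in KO2, with no call for the list (camera adjusted p = 0.467 and 0.459) and a median of -0.07 and -0.06 that became 0.07 in each with library totals. Besides KAT5, MRGBP (-0.73 and -0.69), MEAF6 (-0.49 and -0.41), RUVBL1 (-0.38 and -0.34), TRRAP (-0.24 and -0.26), BRD8 (-0.19 and -0.10), RUVBL2 (-0.15 and -0.19) and ACTL6A (-0.09 and -0.07) were lower in both lines. DMAP1 (0.74 and 0.67), EPC1 (0.47 and 0.44), EPC2 (0.37 and 0.33) and ING3 (0.27 and 0.28) were higher in both. MORF4L2 (0.09) and VPS72 (-0.10) were called in KO1 alone, and the difference between the lines was not called for either (adjusted p = 0.34 for MORF4L2). With library totals the calls of ACTL6A, BRD8, RUVBL2 and VPS72 were lost, and ACTL6A turned to 0.04 and 0.06. VPS72 in both lines and BRD8 in KO2 also turned slightly positive. The calls of VPS72 in KO1 and ACTL6A in KO2 were lost under several filters too.

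Abundant genes fell more often than others, so the lists were also set beside genes of like level, a comparison chosen after the data had been seen and not tested. Members were lower than the median of such genes by 0.27 in each line for ribosome biogenesis, 0.27 and 0.28 for MYC targets, 0.18 and 0.13 for ribosomal protein and 0.16 and 0.12 for mitosis genes (median differences on the log2 scale). The numbers lower were 38 and 40 against 23.5 and 23.4 for biogenesis and 50 and 51 against 36.4 and 37.4 for ribosomal protein genes. They were 28 and 27 against 20.6 and 20.8 for mitosis genes, and 20 in each against 15.7 and 15.8 for MYC targets. The excess was small for repair (0.10 in each) and oxidative phosphorylation genes (0.07 and 0.04), where 22 and 21 of 32 were lower against 17.4 and 17.2 and 18.8 and 18.9 at like level. For tRNA synthetases (16 lower in each, against 13.6 and 13.8), DNA replication (25 and 23, against 20.3 and 20.4) and heat shock genes (9 in each, against 8.4 and 8.6) the number lower was above that of such genes by a few at most, as for MYC targets. Their median differences were -0.12 in each line, -0.12 and -0.11, and -0.24 and -0.20, and that of other acetyltransferase genes was -0.13 in each. By this measure heat shock genes lay further below such genes than ribosomal protein genes did. Housekeeping genes stood above genes of like level by 0.07 and 0.10. TIP60 complex genes were called about as often as such genes. In KO1 5 were higher and 9 lower, against 4.3 and 10, and in KO2 4 and 8, against 4.2 and 9.9. Leukocyte markers were higher in 4 cases in each line, against 3 and 2.6. Endothelial markers were higher in 6 and 5 cases, against 2.5 and 2.3, and fibroblast markers in 5 and 4, against 1.4 in each. Matrix, junction and lysosome genes stood above theirs by 1.07 and 0.99, 0.90 and 0.86, and 0.45 and 0.43.

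Across all genes, 12816 were called in KO1 (6626 higher and 6190 lower) and 12399 in KO2 (6422 higher and 5977 lower). Rises of at least 2-fold outnumbered falls of that size by 2666 to 184 in KO1 and 2466 to 155 in KO2, and EDIL3, CPA4 and TGFBI stood among them. In the same direction in both, 5751 genes were higher and 5474 lower, against 1867 and 1623 for independent lists of these sizes. The direction went with level: of 8062 genes with a mean log2 CPM under 0, 1529 were higher and 100 lower in both, and of 3812 genes at 6 and over, 703 were higher and 2326 lower. Their log2 fold changes correlated across genes at r = 0.925 (genes are not independent replicates), with a covariance of 0.733. Simulations of unchanged groups against shared controls gave r = 0.501, a covariance of 0.0525 and 0 shared edgeR calls (10 simulations). Part of the excess may come from the shared controls, since 3 controls cannot be split. With library totals in place of TMM, all genes shifted by 0.133 (KO1) and 0.135 (KO2), and the share of calls that were higher went from 51.7% to 67.8% and from 51.8% to 68.9%.

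Full-length TIP60 put back into KO1 moved most of these genes the other way. EDIL3 fell by 3.66 ± 0.10 on the log2 scale to 2.25 ± 0.07 CPM, CPA4 by 3.23 ± 0.08, NRCAM by 2.64 ± 0.09 and EPHB2 by 2.61 ± 0.06 (adjusted p of at most 1.31e-22), and NEO1, CALB2, NPTXR, ZCCHC24, TGFBI and FN1 followed with falls of 1.94 or more. Among genes with a mean log2 CPM of at least 3, TEAD2 rose most besides KAT5, by 1.78 ± 0.06 to 31.8 ± 2.13 CPM (adjusted p = 5.07e-22), then the interferon-induced gene IFIT2 (1.44 ± 0.08), the carbonic anhydrase-related gene CA11 (1.42 ± 0.07) and MEX3A (1.40 ± 0.09). TNNT1, ETV4, GRIN2D, ANP32E and the lipid carrier gene APOE (1.16 ± 0.08) also rose. IFIT2 overlaps LIPA on the opposite strand. SPP1 rose by only 0.56 ± 0.07 and stayed at 19.1 ± 0.43 CPM. Of the TIP60 complex, MRGBP (0.62), MEAF6 (0.47), TRRAP (0.28), RUVBL1 (0.24), BRD8 (0.23) and MBTD1 (0.20, not called with library totals) rose with KAT5, and DMAP1 (-0.69), ING3 (-0.41), EPC1 (-0.39), EPC2 (-0.25) and MORF4L2 (-0.10) fell. That list as a whole was not called (camera adjusted p = 0.158), and its median of 0.05 became -0.05 with library totals.

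With FL, ribosome biogenesis genes rose (37 of 40 higher, median 0.37, camera adjusted p = 9.2e-18; FBL 0.54), as did MYC targets (19 of 25 higher and 2 lower, 0.37, adjusted p = 2.67e-08; HSPD1 0.69), tRNA synthetases (15 of 20 higher and 2 lower, adjusted p = 1.1e-07; EPRS1 0.57) and other acetyltransferase genes (15 of 21 higher and 2 lower, adjusted p = 7.64e-05; MSL1 0.76). Matrix genes fell (22 of 26 lower and 2 higher, median -0.98, adjusted p = 3.85e-10; FN1 -1.94), as did junction genes (13 of 18 lower and 1 higher, -0.73, adjusted p = 0.00035; KRT8 -0.92). Ribosomal protein genes were higher in 48 of 52 cases (0.24, adjusted p = 1.52e-19; adjusted p = 0.0945 with an estimated correlation) and mitosis genes in 24 of 32 (0.22, adjusted p = 1.63e-07; adjusted p = 0.13 with an estimated correlation). Interferon-stimulated genes were higher in 15 of 29 cases and lower in 4 (0.38, adjusted p = 0.00776; adjusted p = 0.13 with an estimated correlation), with IFIT1 at 1.49 and OASL at 2.05. Fibroblast markers were lower in 5 of 6 cases (adjusted p = 0.0302; adjusted p = 0.0798 with an estimated correlation), including COL1A1 at -1.86, and neuroendocrine markers in 5 of 8 (adjusted p = 0.0448; adjusted p = 0.129 with an estimated correlation; CHGA -2.51). Other called lists rose (DNA replication, repair, heat shock, housekeeping, stress response, oxidative phosphorylation) or fell (histones, lysosome, mesenchymal, TGF-beta targets), all with adjusted p from 0.0774 to 0.356 with an estimated correlation. With p-values adjusted over the list alone, 38 biogenesis genes and 20 MYC targets were higher and 14 junction genes lower. In all, 5743 genes were higher and 6233 lower than in KO1, so that 48% of calls were higher, against 33.8% with library totals, which shifted all genes by -0.104.

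FL cells still differed from ctl. SPP1 remained lower, by 1.25 ± 0.07 on the log2 scale (adjusted p = 5.09e-15), and CPA4 and CALB2 higher (0.79 each). Interferon-stimulated genes rose (16 of 29 higher, median 0.36, camera adjusted p = 1.53e-16), with IFI6 and IFIT2 at 0.79 each and OASL at 1.42. That list had no call in the knockouts (medians -0.06 in KO1 and 0.02 in KO2), so this was not a knockout change left over. IFIT2 stood at 11.4 CPM in ctl, 7.29 in KO1 and 19.8 in FL. No KO1 cells with an empty vector were analysed here, so an effect of the vector cannot be told apart. Junction genes (8 of 18 higher, 0.34, adjusted p = 3.17e-07; DSP 0.54) and integrated stress response genes (9 of 22 higher, 0.11, adjusted p = 6.77e-09; SLC7A11 0.44) rose too, and ribosomal protein genes fell (48 of 52 lower, -0.16, adjusted p = 2.52e-57; RPS3 -0.52). MYC targets (13 of 25 lower, adjusted p = 2.66e-13; HSPD1 -0.18) and DNA replication genes (12 of 34 lower and 1 higher, adjusted p = 8.27e-07; RRM2 -0.26) were lower, and mitosis genes in 19 of 32 cases (-0.11, adjusted p = 1.34e-12; adjusted p = 0.0589 with an estimated correlation). TGF-beta targets (9 of 17 higher and 1 lower, adjusted p = 1.31e-07), histone genes (7 of 16 higher, adjusted p = 4.28e-05) and matrix genes (8 of 26 higher and 3 lower, adjusted p = 0.00508) rose. Heat shock (8 of 13 lower, adjusted p = 2.58e-08) and cholesterol biosynthesis genes (9 of 23 lower, adjusted p = 1.2e-05) fell. Lists of lysosome, mesenchymal and mitochondrially encoded genes pointed up and of ribosome biogenesis, oxidative phosphorylation, repair and glycolysis genes down (adjusted p = 0.0522 to 0.185 with an estimated correlation). Adjusted over the list alone, 18 interferon, 10 junction, 10 stress response, 10 TGF-beta, 9 histone and 9 matrix genes were higher and 51 ribosomal protein, 19 MYC target, 16 replication, 23 mitosis, 10 cholesterol and 4 matrix genes lower. In all, 1316 genes were higher and 1715 lower, 43.4% of calls being higher with TMM and 61.6% with library totals. A fit of only these groups called 1995 genes instead of 3031.

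Y47A cells differed from FL cells in many of the genes that the knockout had changed. Against FL, among genes with a mean log2 CPM of at least 3, ZCCHC24 (3.01 ± 0.08), the growth factor binding protein gene IGFBP4 (2.99 ± 0.07), EDIL3 (2.75 ± 0.11), SPECC1 (2.72 ± 0.09) and NRCAM (2.70 ± 0.09) were highest (adjusted p of at most 2.34e-21), followed by CPA4, NECTIN1, NEO1, CAMK2N1 and EPHB2. SPP1 was lower by 2.52 ± 0.08 on the log2 scale, at 3.33 ± 0.21 CPM, and APOE (-1.48), TEAD2 (-1.47), VGF (-1.36), ADGRB1 (-1.29), CA11, the actin-binding gene CALD1, THBS3, CFAP57 and the matricellular gene CCN2 (-1.15 ± 0.05) were lower. CCN2 had not been called in KO1 against ctl (0.10 ± 0.05) and was at -0.19 ± 0.05 in KO2, so most of its fall was not a knockout change. THBS3 overlaps MTX1 and CFAP57 overlaps EBNA1BP2 on the opposite strand. All 40 biogenesis genes (median -0.43, camera adjusted p = 4.29e-24; FBL -0.55) and all 52 ribosomal protein genes (-0.31, adjusted p = 2.68e-32; adjusted p = 0.0606 with an estimated correlation) were lower. MYC targets fell (21 of 25 lower and 2 higher, adjusted p = 3.2e-11; RCC1 -0.71), as did replication genes (23 of 34 lower and 4 higher, adjusted p = 5.86e-06; CDC6 -0.54), and matrix genes rose (17 of 26 higher and 5 lower, 0.78, adjusted p = 8.82e-05; COL6A1 1.94) with junction genes (13 of 18 higher and 2 lower, adjusted p = 0.00209; DSP 1.53). Mitosis genes went both ways (12 higher and 9 lower of 32, adjusted p = 0.914; CCNB1 0.24 and KIF23 -0.31), with a median of 0.01. tRNA synthetase genes fell (17 of 20 lower and 2 higher, adjusted p = 3.95e-08). Leukocyte markers were higher in 5 of 8 cases (adjusted p = 0.0548; ITGAM 1.19). Of the other called lists, lysosome and mesenchymal genes pointed up and repair, stress response, heat shock, YAP/TEAD, acetyltransferase, housekeeping and cholesterol genes down (adjusted p = 0.0983 to 0.148 with an estimated correlation). The medians of the last 3 (-0.11, -0.11 and -0.09) turned positive with library totals. With p-values adjusted over the list alone, 3 MYC targets, 19 matrix, 14 junction and 6 leukocyte genes were higher. In all, 5864 genes were higher and 5609 lower, 51.1% of calls being higher with TMM and 69.5% with library totals (shift 0.114).

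The dN form gave a like picture against FL, again ranked among genes with a mean log2 CPM of at least 3. SPECC1 (3.10 ± 0.09), ZCCHC24 (3.08 ± 0.08), IGFBP4 (3.04 ± 0.07), CPA4 (3.03 ± 0.08) and NRCAM (2.82 ± 0.09) were highest (adjusted p of at most 1.81e-23), and NEO1, NECTIN1, EDIL3, CAMK2N1 and CALB2 followed. SPP1 (-2.55 ± 0.09, 3.19 ± 0.63 CPM), the neuronal microtubule gene MAP2 (-1.77 ± 0.06), TEAD2 (-1.69 ± 0.07) and APOE (-1.66 ± 0.08) were lowest, with VGF, CA11, THBS3, ADGRB1, the nuclear receptor gene NR2F1 (-1.29 ± 0.08) and TNNT1. MAP2 had not been lowered in the knockouts (0.00 ± 0.05 in KO1 and 0.31 ± 0.05 in KO2 against ctl). Its fall was one below KO1, by 2.06 ± 0.06 with dN and 1.40 ± 0.06 with Y47A. NR2F1 overlaps its antisense transcript. All 40 biogenesis (median -0.49, camera adjusted p = 7.3e-25; NIP7 -0.87) and 52 ribosomal protein genes (-0.42, adjusted p = 1.3e-36; RPL22 -0.51) fell, with MYC targets (20 of 25 lower and 1 higher, adjusted p = 9.33e-14; HSPE1 -0.87) replication genes (27 of 34 lower and 1 higher, adjusted p = 8.91e-11; MCM3 -0.51) and tRNA synthetases (17 of 20 lower and 2 higher, adjusted p = 1.61e-08). Matrix (15 of 26 higher and 5 lower, 0.86, adjusted p = 0.000189; LOXL2 1.22) and junction genes (10 of 18 higher and 2 lower, 0.85, adjusted p = 0.0054; JUP 1.55) rose. Mitosis genes were higher in 20 of 32 cases and lower in 7 (0.13, adjusted p = 0.00849; adjusted p = 0.536 with an estimated correlation; CCNB1 0.43). Of the other called lists, lysosome genes pointed up and repair, heat shock, YAP/TEAD, acetyltransferase, housekeeping and oxidative phosphorylation genes down (adjusted p = 0.0655 to 0.476 with an estimated correlation). With library totals the median of acetyltransferase genes (-0.14) became 0.00 and those of the last pair (-0.09 and -0.10) turned positive. Adjusted over the list alone, 17 matrix genes were higher and 21 MYC targets and 29 replication genes lower. In all, 6236 genes were higher and 5763 lower, 52% of calls being higher with TMM and 70.2% with library totals (shift 0.132). Of the calls against FL, 5282 were higher and 4999 lower with both forms, against 1604 and 1418 for independent lists; r across genes was 0.928 (0.503 simulated) and the covariance 0.771 (0.0545 simulated). Part of the excess may come from the shared FL libraries.

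Against KO1, both altered forms changed genes, though only partly those that FL moved. Of the genes that changed most with FL, EDIL3 fell by 0.91 ± 0.08 with Y47A and by 1.09 ± 0.09 on the log2 scale with dN, ETV4 rose by 0.64 and 0.68 (± 0.07 each) and ANP32E by 0.33 and 0.36. TEAD2 rose by 0.31 ± 0.07 with Y47A (adjusted p = 0.000481) but was at 0.10 ± 0.07 with dN (adjusted p = 0.333), and the forms were not told apart for it (adjusted p = 0.0977). NEO1 (0.01 and 0.30), NRCAM (0.06 and 0.18), CALB2 (-0.28 and 0.00), CPA4 (-0.53 and -0.20), EPHB2 (-0.37 and -0.30), TGFBI (-0.26 and -0.49), FN1 (-0.18 and -0.46) and NPTXR (-0.20 and -0.22) differed from KO1 by at most 0.53 in size, and ZCCHC24 moved further from ctl (1.02 and 1.09). Among the genes raised by FL, IFIT2 rose with both (0.37 and 0.68) and APOE fell with both (-0.31 and -0.49), while CA11 was called with neither (0.18 and 0.04). MEX3A (0.38), TNNT1 (0.21) and GRIN2D (0.21) rose with Y47A and were not called with dN (0.23, 0.06 and 0.03), but the forms were not told apart for them (adjusted p = 0.456, 0.12 and 0.247). SPP1 fell below its knockout level (-1.96 ± 0.08 and -1.99 ± 0.09), as did CCN2 (-1.25 and -1.32, ± 0.05 each). In all, 2994 genes were higher and 2597 lower with Y47A, and 3155 higher and 3019 lower with dN (51.1% of calls higher with TMM, 61.2% with library totals). Y47A shared 1662 higher and 1534 lower calls with FL (754 and 710 for independent lists), with 1155 opposite. For dN these were 1473 and 1378 (795 and 826), with 1768 opposite. Across genes r with FL was 0.213 for Y47A (0.499 simulated) and 0.097 for dN (0.472 simulated). The covariance was 0.0851 for Y47A (0.0512 simulated) and 0.0413 for dN (0.0508 simulated). That of dN did not exceed what shared KO1 libraries alone gave.

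Mitosis genes rose over KO1 with both altered forms. They were higher in 30 of 32 cases with Y47A (median 0.21, camera adjusted p = 8.18e-23) and 31 with dN (0.29, adjusted p = 2.12e-33), with the kinase gene PLK1 at 0.48 and 0.64 and the cyclin gene CCNB2 at 0.32 and 0.50. YAP/TEAD targets fell (15 of 19 lower and 1 higher with each, medians -0.25 and -0.39, adjusted p = 1.41e-13 and 7.93e-13), with CCN2, DLC1 (-0.67 and -0.59) and AMOTL2 (-0.55 and -0.63). Histone genes (10 and 9 of 16 lower, -0.49 and -0.48, adjusted p = 9.78e-09 and 3.62e-07; H2AC6 -0.84 and -0.68), TGF-beta targets (11 of 17 lower and 1 higher with each, adjusted p = 2.64e-09 and 4.28e-09) and cholesterol biosynthesis genes (13 of 23 lower with Y47A, 12 lower and 1 higher with dN, adjusted p = 2.64e-09 and 8.65e-06; SQLE -0.41 and -0.38) fell too. Matrix genes were lower in 13 and 14 of 26 cases and higher in 4 (adjusted p = 9.02e-05 and 2.71e-05), although COL6A1 rose by 0.96 and 0.84. Hypoxia and glycolysis genes rose with Y47A (18 of 27 higher and 2 lower, adjusted p = 9.24e-10); with dN 10 were higher and 2 lower (adjusted p = 0.025; adjusted p = 0.361 with an estimated correlation), and HK1 rose by 0.64 and 0.71. Ribosome biogenesis genes were lower in 15 of 40 cases and higher in 1 with Y47A (-0.09, adjusted p = 9.02e-05; adjusted p = 0.159 with an estimated correlation) and lower in 24 with dN (-0.13, adjusted p = 6.89e-11; UTP20 -0.34), opposite to their rise with FL. DNA replication genes fell with dN (23 of 34 lower, -0.15, adjusted p = 6.59e-11; MCM6 -0.36), and with Y47A 9 were lower and 4 higher (adjusted p = 0.282). MYC targets fell with dN as well (12 of 25 lower and 1 higher, adjusted p = 3.46e-07; TFRC -0.40). Interferon-stimulated genes were higher in 11 and 12 of 29 cases and lower in 1 (adjusted p = 0.000193, or adjusted p = 0.0681 with an estimated correlation, for Y47A and 2.71e-05 for dN; UBE2L6 0.69 and 0.66). Fibroblast markers were not called (adjusted p = 0.389 and 0.237; COL3A1 -2.97 and -3.35). With p-values adjusted over the list alone, 31 mitosis genes were higher with each form, and 16 YAP/TEAD targets with Y47A, 13 TGF-beta targets with each and 15 (Y47A) and 13 (dN) cholesterol genes were lower, as were 14 matrix genes with Y47A and 19 and 26 biogenesis genes; 13 interferon-stimulated genes were higher with each. The forms shared 2327 higher and 1957 lower calls (414 and 344 for independent lists), with r = 0.738 across genes (0.487 simulated) and a covariance of 0.174 (0.0511 simulated); part of the excess may come from the shared KO1 libraries. No KO1 library without added TIP60 but with its vector was analysed here.

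Genes of other histone acetyltransferases and their partners rose over KO1 with Y47A (10 of 21 higher, median 0.14, camera adjusted p = 0.000292), the direction they took with FL. With dN, 10 were higher and 2 lower (0.08, adjusted p = 0.0112; adjusted p = 0.0723 with an estimated correlation). Ribosomal protein genes were lower in 26 of 52 cases and higher in 1 with Y47A (-0.07, adjusted p = 4.45e-09; adjusted p = 0.395 with an estimated correlation). They were lower in 44 with dN (-0.14, adjusted p = 3.91e-28; adjusted p = 0.0571 with an estimated correlation), opposite to FL. Mitochondrially encoded genes were lower in 5 and 8 of 13 cases (adjusted p = 0.000286 and 0.000325; adjusted p = 0.469 and 0.361 with an estimated correlation). With dN, repair genes (9 of 32 lower and 1 higher, adjusted p = 0.0271; adjusted p = 0.327 with an estimated correlation) and heat shock genes (7 of 13 lower and 1 higher, adjusted p = 0.00308; adjusted p = 0.256 with an estimated correlation) were lower. In counts adjusted over the list alone, 12 and 11 acetyltransferase genes were higher and 2 and 3 lower with Y47A and dN, 28 and 48 ribosomal protein genes and 8 and 9 mitochondrially encoded genes were lower. In dN 10 repair and 8 heat shock genes were then lower and 2 heat shock genes higher.

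**Figure D4:**
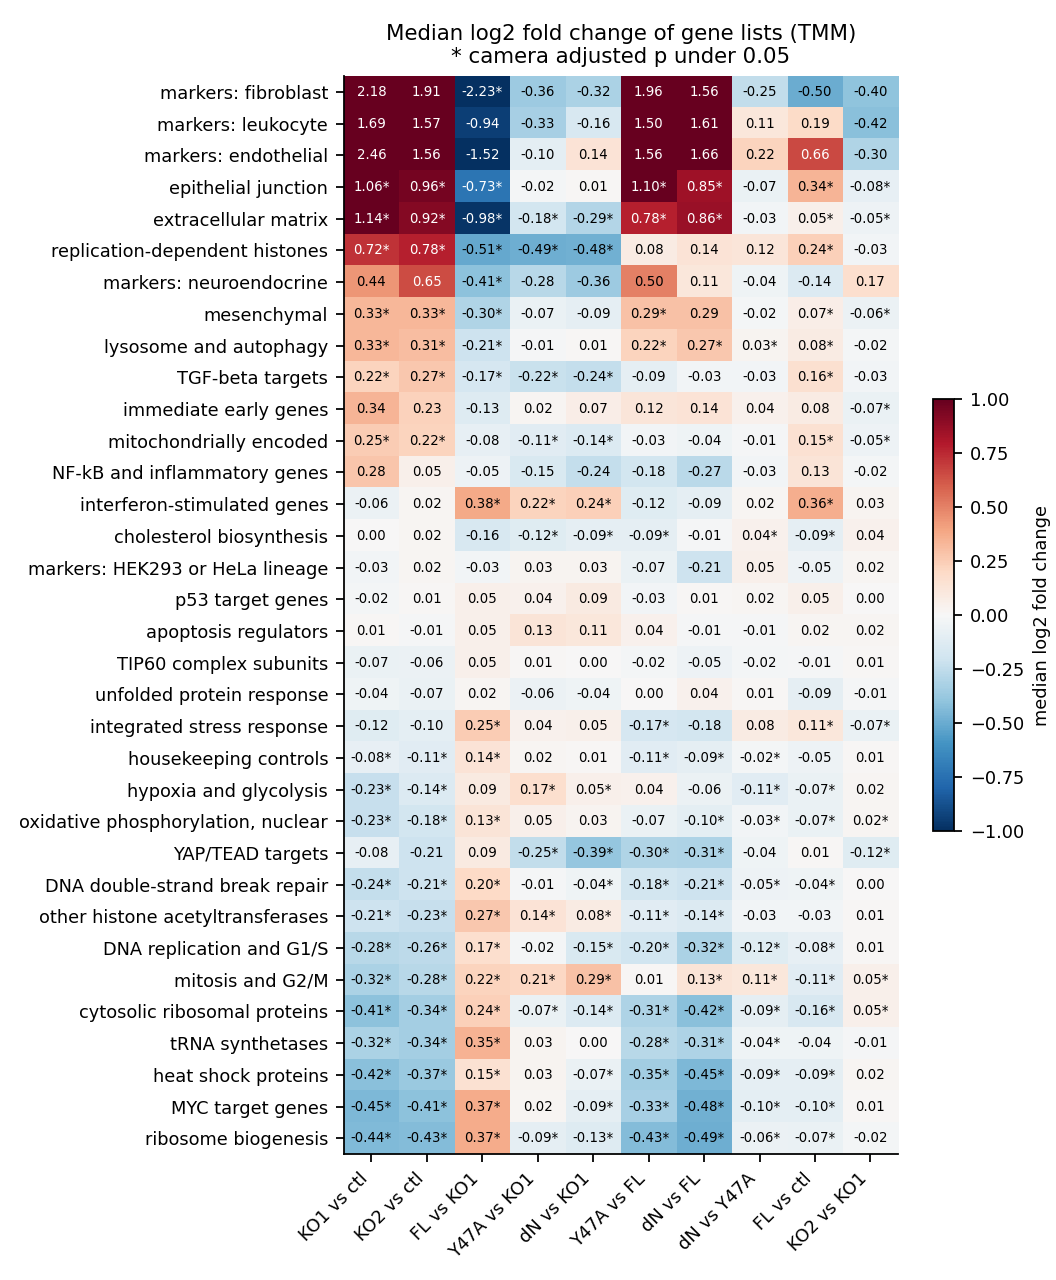
Median log2 fold change (colour and number) of each fixed gene list in each comparison with TMM scaling; an asterisk marks a camera adjusted p under 0.05, which many lists lose with an estimated correlation. Ribosome biogenesis stands at -0.44 and -0.43 in the knockouts, 0.37 in FL vs KO1 and -0.43 and -0.49 in Y47A and dN vs FL; the knockout medians of the housekeeping and TIP60 complex lists turn positive with library totals.

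Restoration was counted on the 12399 genes called in KO2, a line that the rescues were not made from. FL moved 9835 of them (79.3%) back towards ctl, with EDIL3, TGFBI and TEAD2 among them, Y47A 2907 (23.4%) and dN 2544 (20.5%), while 1425 (11.5%) and 2158 (17.4%) moved further from ctl with Y47A and dN. Their median change, signed so that the knockout direction is positive, was -0.37 with FL, -0.05 with Y47A and -0.02 with dN, against 0.44 in KO2. Compared directly, 8908 (71.8%) lay on the knockout side of FL with Y47A, including SPP1 and FN1, and 9148 (73.8%) with dN. A score per library, the mean log2 CPM of the genes raised in KO2 minus that of the genes lowered, was -4.04 ± 0.01 in ctl, -2.71 ± 0.01 in KO1, -3.81 ± 0.01 in FL, -2.80 ± 0.01 in Y47A and -2.71 ± 0.02 in dN (SD, n = 3). The difference from KO1 was -1.101 for FL, which is -83.2% of the step from ctl to KO1 (1.324), -0.082 for Y47A (-6.2%) and 0.008 for dN. An exact two-sided permutation test gave p = 0.1 for FL and Y47A, the smallest that 3 libraries against 3 allow, and p = 0.6 for dN (adjusted over 6 pairs, 0.12, 0.12 and 0.6). Y47A and dN exceeded FL by 1.019 and 1.109, and dN exceeded Y47A by 0.09 (exact permutation p = 0.1 each, adjusted 0.12). The small difference of dN from KO1 was 0 without dN replicate 1 and 0.02 without dN replicate 3. It was -0.012 on the genes called in both knockouts, a set chosen partly on KO1 itself, which biases the difference downwards. It was 0.1 on KO2 genes of at least 2-fold, on which dN exceeded Y47A by 0.202.

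**Figure D5:**
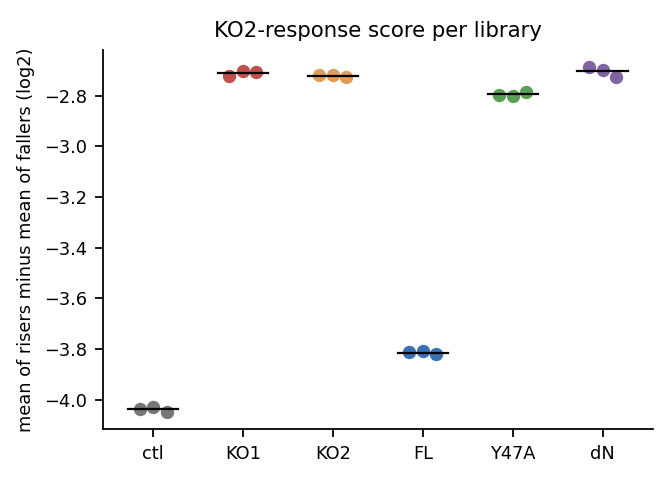
KO2-response score of each library (mean log2 CPM of genes raised in KO2 minus mean of genes lowered), with a bar at the mean of the 3 libraries of a group. FL libraries (mean -3.81) lie near ctl (-4.04), and Y47A (-2.80) and dN (-2.71) near KO1 (-2.71); ctl and KO2 chose the genes and were not tested.

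The altered forms differed from each other in fewer genes, 448, of which 4 by at least 2-fold. The knockout lines KO2 and KO1 differed in 306, of which 2 by at least 2-fold. The labels name 1 group of cells per form. A difference between forms, FL included, therefore cannot be told apart from a difference between the derived cells. With dN, MAP2 was lower than with Y47A (-0.65 ± 0.06, adjusted p = 5.37e-08), and NR2F1 (-0.43 ± 0.08), FN1 (-0.29 ± 0.04) and TGFBI (-0.23 ± 0.03) were lower, while SPECC1 (0.39 ± 0.08), CPA4 (0.33 ± 0.07) and the desmosome gene DSP (0.28 ± 0.03) were higher. DNA replication genes fell (20 of 34 lower, median -0.12, camera adjusted p = 1.19e-27; MCM7 -0.19), with MYC targets (10 of 25 lower, adjusted p = 7.44e-19; SRM -0.21), ribosomal protein genes (15 of 52 lower, adjusted p = 4.44e-39; RPL8 -0.13) and hypoxia and glycolysis genes (9 of 27 lower, adjusted p = 2.22e-15; GPI -0.22). Heat shock (5 of 13 lower, adjusted p = 2.3e-11) and ribosome biogenesis genes (5 of 40 lower, adjusted p = 1.83e-10) fell too. Mitosis genes rose (10 of 32 higher, 0.11, adjusted p = 2.24e-22; HMMR 0.22). Other called lists pointed up (cholesterol, lysosome) or down (housekeeping, repair, tRNA synthetase, oxidative phosphorylation; adjusted p = 0.0647 to 0.322 with an estimated correlation). Adjusted over the list alone, 24 replication genes, 17 MYC targets, 43 ribosomal protein, 16 glycolysis, 7 heat shock and 12 biogenesis genes were lower and 26 mitosis genes higher and 1 lower. In all, 172 genes were higher and 276 lower (38.4% of calls higher with TMM, 63.2% with library totals). The count of 448 became 209 and 167 without Y47A replicates 1 and 2, 233, 297 and 241 without dN replicates 1, 2 and 3, 987 with DESeq2 and 1024 in a fit of only these groups.

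The knockout lines differed in 306 genes, 145 higher and 161 lower in KO2. TEAD2 was less reduced in KO2 (0.48 ± 0.07 above KO1, adjusted p = 7.22e-05), as were SPP1 (0.31 ± 0.07) and SERPINH1 (0.24 ± 0.04), and MAP2 was higher (0.31 ± 0.05), whereas EDIL3 was at the same level (-0.01 ± 0.08, adjusted p = 0.993). YAP/TEAD targets fell (5 of 19 lower, 11 lower and 1 higher adjusted over the list alone, median -0.12, camera adjusted p = 1.58e-11; CCN2 -0.29), with matrix genes (4 of 26 lower, 7 adjusted over the list alone, -0.05, adjusted p = 4.13e-05) and junction genes (3 of 18 lower, 6 adjusted over the list alone, -0.08, adjusted p = 4.13e-05; DSP -0.22). Ribosomal protein genes were higher in 9 of 52 cases (20 adjusted over the list alone, 0.05, adjusted p = 1.86e-25; adjusted p = 0.112 with an estimated correlation; RPS3 0.15). Mesenchymal genes fell as a list (1 of 17 lower, 2 adjusted over the list alone, -0.06, adjusted p = 0.000778). Other called lists pointed up (mitosis, oxidative phosphorylation) or down (immediate early, stress response, mitochondrially encoded; adjusted p = 0.102 to 0.539 with an estimated correlation). The count of 306 became 97, 199 and 176 without KO1 replicates 1, 2 and 3, 90 and 121 without KO2 replicates 1 and 2, 575 with DESeq2 and 540 in a fit of only these groups.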

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

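The comparison of KO2 with KO1 and the regrouping of libraries were planned before the data were examined, and no test in this part was chosen after its result was seen. The knockout lines differed in 306 genes. Among the genes named for the knockouts, CPA4 (-0.29), CALB2 (-0.36), EPHB2 (-0.24), BHLHE40 (-0.24) and ZCCHC24 (-0.32) were less raised in KO2, on the log2 scale. The lowered genes SPP1 (0.31), TEAD2 (0.48), ANP32E (0.17) and SERPINH1 (0.24) were less lowered in KO2, so that KO2 lay nearer ctl for all 9.

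Each comparison was repeated with its 6 libraries regrouped in all 10 ways into 3 and 3, which cannot give a share under 0.05. In each comparison 1 of the 10 groupings, the real one, called the most genes with edgeR. Every other grouping mixed libraries of both groups, so a real difference became spread within groups. Few calls there follow from the construction, so the gap in calls does not measure the strength of a difference. The real grouping called 12816 for KO1 with ctl, 12399 for KO2 with ctl, 11976 for FL with KO1, 5591 for Y47A with KO1, 6174 for dN with KO1, 11473 for Y47A with FL and 11999 for dN with FL, against 0 as the highest other value each time. It called 306 for KO2 with KO1, with 0 as the highest other value. For dN with Y47A (448) and FL with ctl (3031) the highest other value was 1.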

How the results depend on the processing

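Alternatives were planned before the data were examined, except thinning of counts to the smallest library and the setting of lists beside genes of like level, which were chosen afterwards. Of 230 counts and scores under other settings 179 stayed near the main value, which does not mean equal to it. A count was taken as near within a fixed factor, and a score within the spread of its libraries. For dN with Y47A, 645 genes without the low-count filter still passed as near 448. With library totals KO1 with ctl had 12783 calls, but 8666 were higher and 4117 lower. Of the values of named genes 2928 kept their sign and their call or lack of it, and 28 did not. DESeq2 called 987 genes for dN with Y47A and 575 for KO2 with KO1. Fitting only the groups compared gave 1024 for dN with Y47A, 1995 for FL with ctl and 540 for KO2 with KO1. At an adjusted p under 0.01 the counts were 167 (dN with Y47A), 1733 (FL with ctl) and 120 (KO2 with KO1), fewer by construction. A 2-fold minimum left 2850 (KO1), 2621 (KO2), 2172 in the same direction, 2466, 430 and 539 (FL, Y47A and dN with KO1), 2413 and 2713 (Y47A and dN with FL), 4 (dN with Y47A), 173 (FL with ctl) and 2 (KO2 with KO1), and 1630, 82 and 75 restored with FL, Y47A and dN. The replicate block gave 12850 for KO1 with ctl (main value 12816), 560 for dN with Y47A and 341 for KO2 with KO1. It called 22 lists for FL with KO1, 13 for Y47A with KO1 and 16 for dN with FL, 1 more each, and among named genes it changed no other call. Thinning to the smallest library gave 12167 for KO1 with ctl and 455 for dN with Y47A. Causes of these differences were not tested where none is given.

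Gene lists called numbered 19 (KO1), 19 (KO2), 21 (FL with KO1), 12 (Y47A with KO1), 16 (dN with KO1), 16 (Y47A with FL), 15 (dN with FL), 13 (dN with Y47A), 19 (FL with ctl) and 10 (KO2 with KO1) with camera. An estimated correlation between genes left 12 (KO1), 13 (KO2), 6 (FL with KO1), 8 (Y47A with KO1) and 10 (dN with KO1). It left 6 and 7 (Y47A and dN with FL), 7 (dN with Y47A), 11 (FL with ctl) and 4 (KO2 with KO1). The self-contained test fry asks another question and called 29, 30, 32, 20, 26, 27 and 28 for KO1, KO2, the 3 forms with KO1 and the 2 altered forms with FL.

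Score differences with a prior count of 0.5 were -1.19 (FL with KO1), 1.107 (Y47A with FL) and 1.198 (dN with FL). On KO2 genes of at least 2-fold they were -1.982, -0.103 and 0.1 for FL, Y47A and dN with KO1, 1.879 and 2.081 for Y47A and dN with FL, and 0.202 for dN with Y47A. On genes called in both knockouts they were -1.168, -0.106 and -0.012 for the forms with KO1, the last with its sign reversed from 0.008. That set was chosen partly on the KO1 libraries, which biases differences from KO1 downwards, so the reversal decides nothing. On the same genes they were 1.062 and 1.156 for Y47A and dN with FL. Without dN replicates 1 and 3 the difference of dN from KO1 was 0 and 0.02.

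Leaving out each library in turn, which lowers the number of libraries by construction, gave 12042 to 12246 genes for KO1 with ctl, 11513 to 11851 for KO2 with ctl, 10576 to 10803 in the same direction, 11177 to 11254 for FL with KO1, 4520 to 4804 for Y47A with KO1, 5230 to 5468 for dN with KO1, 10564 to 10757 for Y47A with FL, 11094 to 11368 for dN with FL and 2195 to 2892 for FL with ctl. For dN with Y47A the range was 167 to 329 and for KO2 with KO1 90 to 215. Restored genes ran from 9340 to 9576 with FL, 2402 to 3022 with Y47A and 2175 to 2573 with dN.

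The named genes whose calls moved had small changes, besides PTPRC at its low level. With library totals ACTL6A went to 0.04 in KO1 and 0.06 in KO2, VPS72 to 0.03 and 0.06 and BRD8 to 0.03 in KO2, all with signs reversed from TMM. The calls of BRD8 in KO1 (-0.06) and RUVBL2 in both (-0.01 and -0.05) and of MBTD1 with FL (0.09) were lost with totals. VPS72 in KO1 and ACTL6A in KO2 also lost their calls under several filters and with only the groups compared, and VPS72 with DESeq2 (-0.10). PTPRC in KO2 was at 1.63 without ctl replicate 1 and 1.79 without KO2 replicate 2, and not called. MORF4L2 in KO2 was called with library totals (0.17) and with a filter at a mean CPM of 1 (0.08). MYC in dN against FL, not called in the analysis reported, was 0.15 without dN replicate 1 and -0.03 without dN replicate 3.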

Other observations

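Several pathways showed opposed changes of single genes in the knockouts without a call for the list. Of 22 p53 targets, 9 were higher and 8 lower in KO1 and 7 and 7 in KO2 (camera adjusted p = 0.96 and 0.966), although H1299 lacks p53. The cell cycle inhibitor gene CDKN1A rose by 1.14 ± 0.04 and 0.94 ± 0.04 and TP53INP1 by 0.93 ± 0.05 and 0.99 ± 0.05, while MDM2 was at -0.78 ± 0.04 and -0.68 ± 0.04. The list median was -0.02 in KO1 (0.12 with library totals) and 0.01 in KO2, where the test pointed down. Of 23 immediate early genes 13 were higher and 7 lower in each line (adjusted p = 0.147 and 0.378), with KLF6 at 1.08 and 0.90 and the signalling inhibitor gene SPRY4 at -0.97 and -0.93. Of 24 apoptosis regulators 8 were higher and 11 lower in KO1 and 7 and 8 in KO2 (adjusted p = 0.848 and 0.858), with BCL2L11 at 0.69 and 0.73 and BCL2L1 at -0.40 and -0.47; the list medians were 0.01 in KO1, against the direction of the test, and -0.01 in KO2, which became 0.12 with library totals. Adjusted over the list alone, these counts were the same but for 8 lower immediate early genes in KO2.

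Stress and lipid genes were likewise divided in the knockouts. Of 22 integrated stress response genes 5 were higher and 9 lower in KO1 and 4 and 9 in KO2 (camera adjusted p = 0.564 and 0.194; VLDLR 0.59 and 0.50, ATF4 -0.24 and -0.31), with medians of -0.12 and -0.10 that became 0.01 and 0.03 with library totals. Among 17 unfolded protein response genes 4 and 5 were higher and 7 and 8 lower (adjusted p = 0.703 and 0.574; SEL1L 0.67 and 0.70), and the medians of -0.04 and -0.07 became 0.09 and 0.07 with library totals. Cholesterol biosynthesis genes were higher in 9 of 23 cases in each line and lower in 8 and 7 (adjusted p = 0.96 and 0.598), with INSIG1 at 0.73 and 0.70 and ACAT2 at -0.92 and -0.80. Of 29 interferon-stimulated genes 9 were higher and 9 lower in KO1 and 9 and 6 in KO2 (adjusted p = 0.848 and 0.55; SAMD9 0.66 and 0.53), with a median of -0.06 in KO1, against the direction of the test, that became 0.08 with library totals. NF-kB genes were higher in 5 and 4 of 19 cases and lower in 6 and 5 (adjusted p = 0.96 and 0.844; SOD2 -0.61 and -0.56, NFKB2 0.48 and 0.35), with positive medians (0.28 and 0.05) where the test pointed down. YAP/TEAD targets were higher in 5 of 19 cases in each line and lower in 8 and 12 (adjusted p = 0.727 and 0.0838; ANKRD1 2.20 and 1.59, NT5E -0.38 and -0.37), with a median of -0.08 in KO1 that became 0.05 with library totals. When adjusted over the list alone, 10 interferon-stimulated and 6 stress response genes were higher in KO1. By class, 4409 of 14848 protein-coding genes were higher and 4752 lower in both knockouts, against 1076 and 130 of 4170 long noncoding genes and 252 and 589 of 3567 pseudogenes.

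The tests against carry-over of genomic DNA, scaling, noise of low counts, an effect of overexpression by itself and unequal transgene mRNA were chosen only after the results were seen; those on depth, shared list members and pseudogenes were written down before their results.

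Far more genes rose than fell by at least 2-fold in both knockouts (2113 against 59), and 3 technical causes were examined. Carry-over of genomic DNA could raise all silent genes, but the rise per kb of 381 olfactory receptor genes was at most 0.0181 of that of the 1329 low-level risers in any knockout library. The excess did not hinge on the choice among 3 scalings, since rises in both were 36.5 times the falls with RLE factors and 88.6 times with library totals. However, RLE gave nearly the median change of TMM in KO1 (0.041 and 0.039), and totals shifted all genes up (by 0.133 in KO1). Neither setting could therefore have ended the excess, and scaling as a cause stays undecided. Noise of low counts left rises as 0.902 of the changes among genes whose log2 CPM midway between ctl and the knockouts was at least 2 (231 against 25). Unspliced RNA was not tested and stays open; counts of intronic reads would be a test.

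Mitosis genes were higher than in KO1 with each of the 3 forms, though for FL not with an estimated correlation (camera adjusted p = 0.13 with an estimated correlation), while ribosome biogenesis genes rose with FL alone. Thinning to the smallest library left the median of dN over KO1 at 0.29. Thinning keeps the expected ratio between libraries, so it could hardly have moved the median and does not decide on depth. A difference in transgene mRNA was small, as dN held 0.973 of the KAT5 mRNA of FL. An effect of TIP60 overexpression whatever the genotype stays open: the mitosis median in FL over ctl was -0.11, but FL cells also carry the knockout, and no ctl cells with added TIP60 or KO1 cells with an empty vector were analysed here. A change in the share of cells in each cell cycle phase was not tested.

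MYC mRNA, a level chosen after its values were seen, was higher in both knockouts (log2 fold change 0.90 in KO1) while MYC target genes were lower, by 0.27 and 0.28 on the log2 scale beyond genes of like level. The fall could come from list members shared with other falling lists, yet the 15 targets in no other list had a median of -0.43 in the line nearer 0. Reads shared with processed pseudogenes could also lower counts, yet the 11 targets without such a pseudogene had a median of -0.41. MYC fell again with each form (-1.01 with FL, -0.78 with Y47A and -0.92 with dN), whereas its targets rose with FL alone. One hypothesis is that MYC target genes need full-length TIP60 as a partner of MYC, which binding maps of MYC and TIP60 would test.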
